A study of Mus musculus with 2 samples.

How the data were processed

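H3K36me3 ChIP-seq was carried out on midbrain of mouse embryos of the C57BL/6 strain B6NCrl at 12.5 days, in 2 biological replicates that pooled 120 and 88 embryos of both sexes, per the labels. Both replicates belong to 1 group. The labels describe them as biological replicates from separate pools, so the spread between them includes biological and technical variation.

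The deposited data used here are 4 peak lists in narrowPeak format on mm10: 1 for each replicate, 1 called on both replicates together (pooled) and 1 named replicated, which was derived from the other 3, per the description files deposited with the samples. Each of the first 3 was called against control libraries, per the same files. The aligner, the peak caller, their versions and the rule for keeping a peak are not given in the sources used here. Each peak has a deposited score that is scaled within its file, which was not used. The deposited signal value of a peak, an enrichment whose scaling is not stated, was used to describe and rank peaks within a list and as a weight in 1 alternative. The deposited −log10 p-value and −log10 q-value of each peak were used for ranking and for a stricter threshold. All of these are the authors' own values. The lowest −log10 p-value was about 2.0 in every deposited list (2.02 in the replicated list), so the lists are inclusive, and 99.5% of replicated peaks, 86.2% of replicate 1 peaks and 80.5% of replicate 2 peaks had a q-value of 0.01 or less. Peak lists hold no read counts, so depth is unknown. The absence of a peak means that none was called, not that the mark was absent. A deeper library or a better enrichment gives more and wider peaks, so replicate differences in covered bases can be technical.

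Peaks were placed on the GENCODE M21 annotation of GRCm38, the build that mm10 names. No peak ended past the end of its chromosome. Chromosomes 1 to 19, X and Y were used, and peaks on other scaffolds were left out of all comparisons. All values were computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Numba 0.67.0, and plots were drawn with Matplotlib 3.10.9.

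A peak counted as shared when at least 50% of its own length lay under the other list, and chance was set by 100 random placements of each peak on its own chromosome. Wilson 95% intervals of these shares were 47.2% to 47.7% for replicate 1 and 71.1% to 71.5% for replicate 2, which cover counting error only. For genomic location each base was given 1 class in the order exon, promoter (1 kb either side of a transcription start), intron, intergenic, over all annotated genes. The percent of the gene body covered was computed for protein-coding genes of at least 1 kb from annotated start to end, without regard to strand, and a gene was called marked at 10% or more. Short genes can hold few bases of a peak and long ones need many, so comparisons of gene lists were matched on length. Coverage along the gene used deciles of the body of marked genes of at least 10 kb. Exon and intron coverage used marked genes with at least 4 exons and left out the first exon and intron. Intergenic clusters were replicated peaks over 5 kb from any gene, merged within 5 kb.

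The median of each of 25 gene lists was set against 10000 random lists of protein-coding genes of the same size and the same length deciles, or 1000 for lists of 300 genes or more. A list was called above these when its median passed the 97.5 percentile. Medians of random lists were often 0, so a low list could not be told from them by its median. For low lists the number of marked members was therefore compared with the same random lists, and this comparison was chosen after seeing the data. Some of 25 lists can pass by chance, and the percentiles describe these libraries and are not tests over samples. Genes are not replicates, and no p-value over genes is given. Values of each replicate's own list give the error (SD, n = 2), which with so few replicates is imprecise. With 1 group of 2 there is no comparison of groups and no test of 1.

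The gene lists, the thresholds, the alternatives and the rule for genes named in the text were fixed before the data were examined. The rule took the 10 genes of at least 20 kb with the highest percent covered, the 10 genes with most covered bases, of each list the 2 highest and the 2 lowest members (ties in alphabetical order), every gene of the H3K36 list, the 10 genes of at least 10 kb and 10% mean coverage that differed most between replicates, and the 5 intergenic clusters with most covered bases. Genes outside it are said to be so where they are named.

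The calculations were tested on simulated data. Of 4200 interval answers 0 differed from a base-by-base count. Of 10 lists of 20 genes drawn from the 21221 genes and raised by 50 points, 10 passed the 97.5 percentile, and of 10 raised by 20 points, 3 did, so modest shifts of short lists can be missed. Of 100 unchanged lists, 5 fell outside the 2.5 to 97.5 percentiles. In these list simulations coverage was first shuffled among genes, which removed any link with gene length. Only medians were simulated, and the comparison by number of marked members was not.

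Alternatives were other overlaps that count as shared, the same number of peaks in both lists, a q-value threshold of 0.01, the pooled list, each replicate's list alone, other thresholds and gene sets for marking, coverage weighted by signal, and random lists matched on GC content as well or not matched. Leaving out genes that overlap another coding gene from the gene lists was added after seeing the data. Read-level analysis, input correction and comparison with other tissues or with expression were not done here.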

Results

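Trimethylation of lysine 36 on histone H3 (H3K36me3) was mapped by ChIP-seq in midbrain dissected from mouse embryos at 12.5 days of gestation. The mark is laid down by SETD2, which travels with elongating RNA polymerase II, and it is commonly read as a sign of transcribed gene bodies. There was 1 group with 2 biological replicates, each a pool of embryos of both sexes: 120 embryos in replicate 1 and 88 in replicate 2. No other tissue, stage or treatment was analysed here, so the comparisons are between the replicates, between parts of genes, and between groups of genes. The files list peaks and give no read counts, so sequencing depth is unknown. Replicate 1 had 180444 peaks over 107.8 Mb and replicate 2 had 163283 peaks over 82.6 Mb. The authors' pooled list, called on both replicates together, had 171539 peaks, and their replicated list kept 96931 of these over 114.8 Mb, or 4.34% of the sequenced genome. Gene values below are the percent of the annotated gene body (mm10) under replicated peaks, followed where useful by the mean ± SD of the 2 replicates' own lists (n = 2). Because peaks called on both replicates together were wider, the first value usually exceeds that mean.

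The first question was whether the 2 pools marked the same places. They largely did where peaks were strong. Of the replicate 2 peaks, 71.3% had at least 50% of their length under a replicate 1 peak, against 4.56% after peaks were moved at random along their chromosomes, a ratio of 15.6. Of the replicate 1 peaks, 47.5% lay under replicate 2, against 3.41% at random, a ratio of 13.9. In the decile of peaks with the best p-values these shares were 98.4% and 93.7%, and in the weakest decile they were 50% and 23.1%. The 2 lists shared 64.5 Mb, 51.2% of all bases in either. These shares depend on the overlap asked for: with 90% of the peak required, 44.4% of replicate 2 peaks and 15.9% of replicate 1 peaks were shared.

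The authors' replicated list was made only of pooled peaks, unaltered. It kept 56.5% of them and 83.8% of their bases, the stronger and wider ones: the median signal value was 3.28 for kept peaks and 2.28 for the rest, and the median width was 741 against 262 bases. It held 73.4% of replicate 1 peaks and 86.1% of replicate 2 peaks. No pooled peak outside the list overlapped a peak of each replicate by 50% of either length, and 85.1% of the kept peaks did.

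H3K36me3 lay inside genes. Exons, introns and promoters together held 95.7% of replicated peak bases (95.7% ± 0.203 in the replicates), although they make up 47.7% of the genome. Exons were the most overrepresented class, with 24.8% of peak bases against 4.84% of the genome, a ratio of 5.13. Introns held 69.2% of peak bases at a ratio of 1.73. Promoter sequence outside exons, within 1 kb of a transcription start, was underrepresented at a ratio of 0.587, and sequence between genes held 4.25% at a ratio of 0.0813. Each class differed from its genomic share by far more than the replicates differed.

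Of 21221 protein-coding genes of at least 1 kb, 8039 (37.9%) were marked, meaning at least 10% of the body was covered, and 10870 had no replicated peak. The replicates' own lists marked 7678.5 ± 555.1 genes (8071 and 7286), with 7208 marked in both. Among marked genes the median was 43.6% of the body, with quartiles of 25.8% and 62.3%. Across genes, which are not independent replicates, the 2 replicates' percents had a Spearman correlation of 0.961 and a Pearson correlation of 0.979. Replicate 1 covered more of the gene in 7487 of the 8039 marked genes, by a median of 7.51 percentage points. Of the marked genes, 2457 overlap another coding gene on either strand, and their coverage cannot be assigned to 1 gene. Of long non-coding RNA genes of at least 1 kb, 9.47% were marked. Outside other coding genes, 112 of 5580 long non-coding RNA genes (2.01%), 9 of 1759 processed pseudogenes (0.512%) and 33.7% of coding genes were marked, with no matching on gene length. These classes are the annotation's own, and some of the 112 carry symbols of coding genes.

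**Figure D1:**
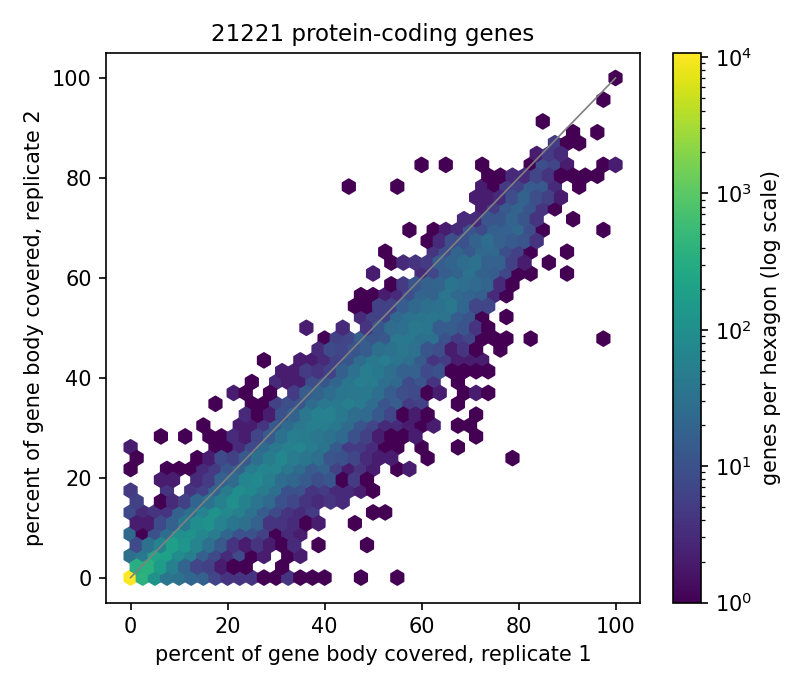
Percent of each protein-coding gene body covered by peaks in replicate 1 (x axis) and replicate 2 (y axis), for 21221 genes; colour gives genes per hexagon on a log scale and the grey line marks equal values. Of the 8039 marked genes, 7487 lie below the line, with more of the gene covered in replicate 1.

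Some genes were covered almost from end to end. Among genes of at least 20 kb the most covered was Sf3a1, a subunit of the splicing factor SF3A, with 94.98% of its body (chromosome 11, 4160350 to 4182541; 86.0% ± 7.08 in the replicates). It was followed by Ints1 of the Integrator complex (94.3%; 86.0% ± 1.48), Trrap, a scaffold of histone acetyltransferase complexes (94.0%; 86.9% ± 3.91), Exosc10, a catalytic subunit of the RNA exosome (93.0%; 89.6% ± 2.78), and Scrib, a cell polarity protein (92.8%; 89.7% ± 1.13). Sf3b3, Lsg1, Glyr1, Kdm4a and Pogk completed the first 10, with 91.6% to 92.4%. Sf3b3 and Pogk overlap another coding gene.

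Some very long genes carried the mark over more than 100 kb. Syne2, which encodes a giant nuclear envelope protein of the spectrin repeat family, had 162.7 kb covered (chromosome 12, 75818134 to 76110926), 55.6% of its body (45.1% ± 7.88). Wdfy3, an autophagy adaptor, had 139.3 kb, the cytoskeletal linker Macf1 126.7 kb, the translation factor Eif4g3 124.2 kb, the ubiquitin ligase Ubr4, which overlaps another coding gene, 122.3 kb and the microtubule regulator Clasp1 117.2 kb. Trio, a guanine nucleotide exchange factor in axon guidance, had 109.5 kb, and Vps13d had 108.1 kb. The annotated gene bodies of Gm20388 (605.4 kb covered) and Fgfr2 (247.7 kb) ranked above these, but span 4435 and 2961 kb and run across other coding genes. Gene length and marking were related in a hump: 21.7% of genes of 1 to 5 kb, 40.4% of those of 5 to 20 kb, 48.0% of those of 20 to 100 kb and 21.2% of longer ones were marked, although 58.9% of the longest class had a peak somewhere.

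Coverage rose from the 5' to the 3' end. Over 6098 marked genes of at least 10 kb, the first decile of the body was 6.38% covered (5.28% ± 1.27), the fifth 46.3% (37.97% ± 6.09) and the ninth 63.5% (52.7% ± 7.14), before 61.2% (50.7% ± 7.26) in the last. The 5 kb upstream of the gene was 7.23% covered and the 5 kb downstream 26.9%. The 3' side was covered 1.90 times as much as the 5' side (1.93 ± 0.0683 in the replicates), and 5301 of the 6098 genes had more coverage on the 3' side. In 4483 genes the first decile held no covered base.

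**Figure D2:**
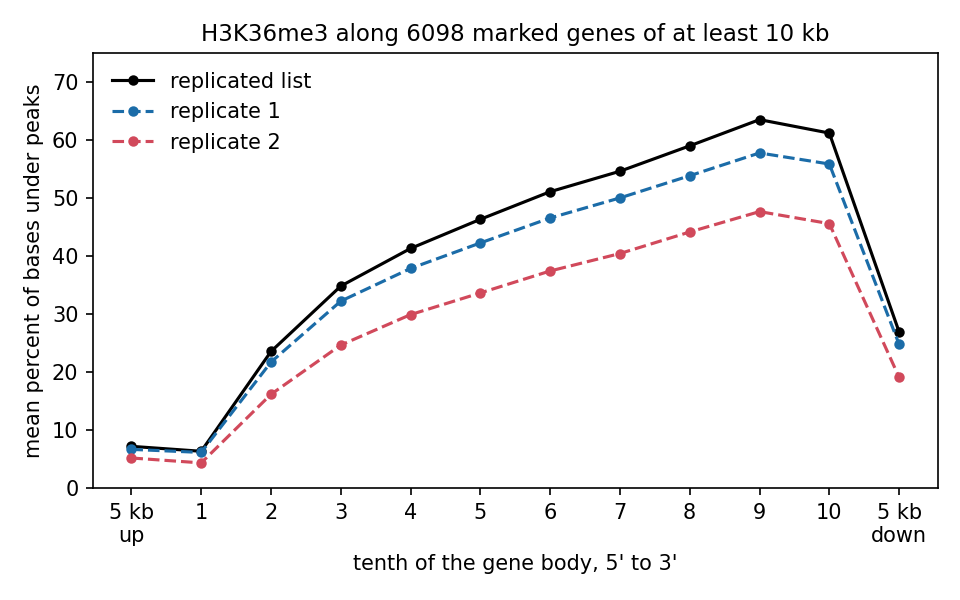
Mean percent of bases under peaks (y axis) in each decile of the gene body from 5' to 3' and in the 5 kb on either side (x axis), over 6098 marked genes, in the replicated list and in each replicate's own list. All 3 lines climb to the ninth decile, which reached 63.5% in the replicated list, and drop downstream, to 26.9% in that list, 24.8% in replicate 1 and 19.1% in replicate 2.

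Within marked genes, exons were covered more than introns. With the first exon and intron left out, 67.3% of exon bases and 46.2% of intron bases were covered in 7193 genes with at least 4 exons, a ratio of 1.45 (1.55 ± 0.0785 in the replicates). Internal exons were 75.8% covered and last exons, many of them long, 59.7%. The ratio was not matched on gene length. Marked genes of over 100 kb had a lower median coverage (22.3% of the body) than those of 5 to 20 kb (51.6%).

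Gene groups differed far more from each other than the replicates did. Splicing factors, cell cycle genes, proteasome subunits, chromatin regulators and ribosomal protein genes were almost all marked. All 30 splicing factors were, with a median of 72.6% of the body covered (59.0% ± 11.5), from Prpf40a at 27.8% to Sf3a1. Of 25 cell cycle genes 24 were marked, median 66.2% (55.1% ± 6.84), led by Mcm5 (85.3%) and Mcm2 (82.9%), parts of the replicative helicase. The exception was Pcna, the DNA polymerase clamp, at 0% in the replicated list (5.15% ± 0.681 in the replicates). Of 30 other chromatin regulators, 28 were marked, median 63.6% (54.1% ± 6.82), led by the remodellers Chd4 (89.6%) and Smarcc2 (88.8%). The exceptions were Smarca2 (2.63%) and Arid1b (8.51%). Of 31 proteasome genes 30 were marked, median 62.7% (55.0% ± 5.02), led by Psmc4 (89.2%) and Psmc1 (82.7%), and Psmd14 had 2.67%. Of 51 ribosomal protein genes 47 were marked, median 58.4% (49.3% ± 5.01), led by Rps3 (80.6%) and Rpl5 (77.8%), which overlaps another coding gene. Rpl10 and Rpl30 had no replicated peak, and Rps23 (8.83%) and Rps14 (6.12%), named because they complete the count, fell short of 10%. In replicate 1 alone 49 were marked, with the X-linked Rpl10 (12.1%) and Rps23 (10.4%) above 10%, and in replicate 2 alone 45. Rps14 overlaps another coding gene. The median of each of these 5 lists was above all 10000 random lists matched on gene length.

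Genes that write, erase or read H3K36 methylation were themselves mostly marked, 19 of 22, with a median of 55.0% (43.7% ± 8.58), also above all 10000 random lists. The demethylase Kdm4a had 91.7% (88.4% ± 2.29) and Kdm4b 63.2%, while Kdm4c had 8.63%, Kdm2a 41.9% and Kdm2b 15.1%. The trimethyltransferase Setd2 had 52.0% (42.7% ± 6.63). The methyltransferases Nsd1, Nsd2, Nsd3 and Ash1l had 64.0%, 62.04%, 42.8% and 48.5%, and Setmar had 17.3%. Among readers, Brpf1 had 81.4%, Psip1 75.5%, Msh6 67.7%, Mtf2 59.0%, Morf4l1 58.0%, Zmynd11 20.7% and Phf19 0%. The elongation factors Supt6 and Iws1 had 75.6% and 63.7%. Of the genes named here, Kdm2b, Nsd2, Ash1l, Psip1, Msh6, Mtf2 and Supt6 overlap another coding gene. Without such genes the list median was 42.8%, at the 99.9 percentile. The de novo DNA methyltransferase Dnmt3a had 22.5% (19.5% ± 2.29) and Dnmt3b 6.996% (7.63% ± 5.97).

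Neural genes were split. Of 22 neural progenitor genes 12 were marked, with a median of 15.3% (12.3% ± 7.45). The RNA-binding protein Msi1 had 79.0% (69.6% ± 5.08) and the receptor Fgfr3 63.5% (53.7% ± 5.77), while the short proneural gene Ascl1 and Fabp7 had 0%. Of 26 pan-neuronal genes 14 were marked, with a median of 11.4% (9.13% ± 2.98). Crmp1, a mediator of semaphorin signals, had 54.1% (48.5% ± 5.49), and Elavl3, a neuronal RNA-binding protein, had 49.0% (41.3% ± 5.79). Both overlap another coding gene. Doublecortin (Dcx), a marker of young neurons, and the synaptic gene Snap25 had 0%. The progenitor median stood at the 99.2 percentile of random lists and the pan-neuronal median at 98.0. Neither list passed the 97.5 percentile when random lists were also matched on GC content (97.3 and 97.4) or not matched at all (93.8 and 91.5), and in replicate 2 alone the pan-neuronal median was at 97.4. In replicate 2 alone the medians were 6.99% and 7.02%, with 10 members of each list marked. By the number of marked members neither list stood above random lists in replicate 2 alone or with genes that overlap another coding gene left out.

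Regional and transmitter identity genes were mostly unmarked, meaning below 10% in midbrain as a whole. A mark carried by few of its cells may have gone uncalled. Only 4 of 26 midbrain and isthmus patterning genes reached 10%: Otx2, which specifies midbrain identity (25.2%; 19.4% ± 4.86), Tal2, which acts in midbrain GABAergic neurons (23.2%; 12.8% ± 9.25), and, named after their values were seen, Dmbx1 (17.1%) and Pax7 (12.1%). Barhl1 and Cnpy1 had 0%. In replicate 2 alone, 2 of the 26 were marked. None of 15 dopaminergic genes was marked, the highest being the transcription factor Pbx1 at 9.91% (8.27% ± 2.62) and Ddc, the decarboxylase that makes dopamine, at 0.337%. Pbx1 passed 10% in replicate 1 alone. Of 15 genes of other transmitter classes only the GABA transporter Slc6a1 was marked (19.3%; 14.96% ± 3.67), with the glutamate transporter Slc17a6 at 3.23%. None of 18 forebrain patterning genes was marked, with Lhx2 highest at 2.92%, and none of 39 Hox genes was, with Hoxa1 and Hoxa10 at 0%. Each of these 5 lists had fewer marked members than 97.5% of random lists, which held 9.35, 5.96, 6.49, 6.35 and 10.6 on average. With genes that overlap another coding gene left out, the midbrain list was no longer below them.

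Few markers of other cell types and tissues were marked. The labels name midbrain and no cell type, so a mark carried by few of its cells may have gone uncalled. No member was marked among 16 endothelial and pericyte genes (highest Pdgfrb at 1.18%), 12 mesenchyme and meninges genes (Col1a1 and Col1a2 at 0%), 16 liver genes (highest F2 at 5.21%), 19 striated muscle genes (highest Ttn at 0.381%) and 14 germ cell genes (highest Dazl at 1.54%). Of 16 mature glia genes, Cnp was marked (76.5%; 73.4% ± 4.96), but it overlaps another coding gene, and Mog followed at 9.61%. Of 16 erythroid genes, Tfrc was marked (63.8%; 49.4% ± 8.22), the transferrin receptor that dividing cells in general also use, and Alas2 had 4.49%. These 7 lists also had fewer marked members than 97.5% of random lists. The microglia and macrophage list did not, with 2 of 15 marked against a random mean of 5.04: Cd68, a gene of 1.94 kb covered throughout, and Cx3cr1 (16.0%), whose annotated body overlaps another coding gene. A further pair of lists with no marked member were the 1344 olfactory and vomeronasal receptor genes, for which random lists averaged 456.0, and 19 replication-dependent histone genes, for which they averaged 4.08. The histone list was not below random lists matched on GC content as well, and 48 of its 67 genes are under 1 kb and were not measured.

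Numbered zinc finger genes, mostly repressors of the KRAB type, were marked in 263 of 365 cases, against a mean of 157.6 in random lists. Their median was 30.5% (26.03% ± 4.85), above all 1000 random lists. Zfp869 was covered throughout (88.6% ± 10.4 in the replicates) and Zfp2 had 90.9% (84.9% ± 2.61), while Zfp114 and Zfp174 had 0%. Of 18 imprinted genes 10 were marked, with a median of 18.5% (15.9% ± 8.03) at the 95.2 percentile, which did not pass 97.5. Nnat, which overlaps another coding gene, had 89.4% (74.2% ± 11.9) and Igf2r 55.5% (45.1% ± 7.29), while Cdkn1c and Dlk1 had 0%. The imprinted median was at the 97.7 percentile in replicate 1 alone, at 93.2 in replicate 2 alone, where it was 10.2%, and at 86.1 without genes that overlap another coding gene.

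**Figure D3:**
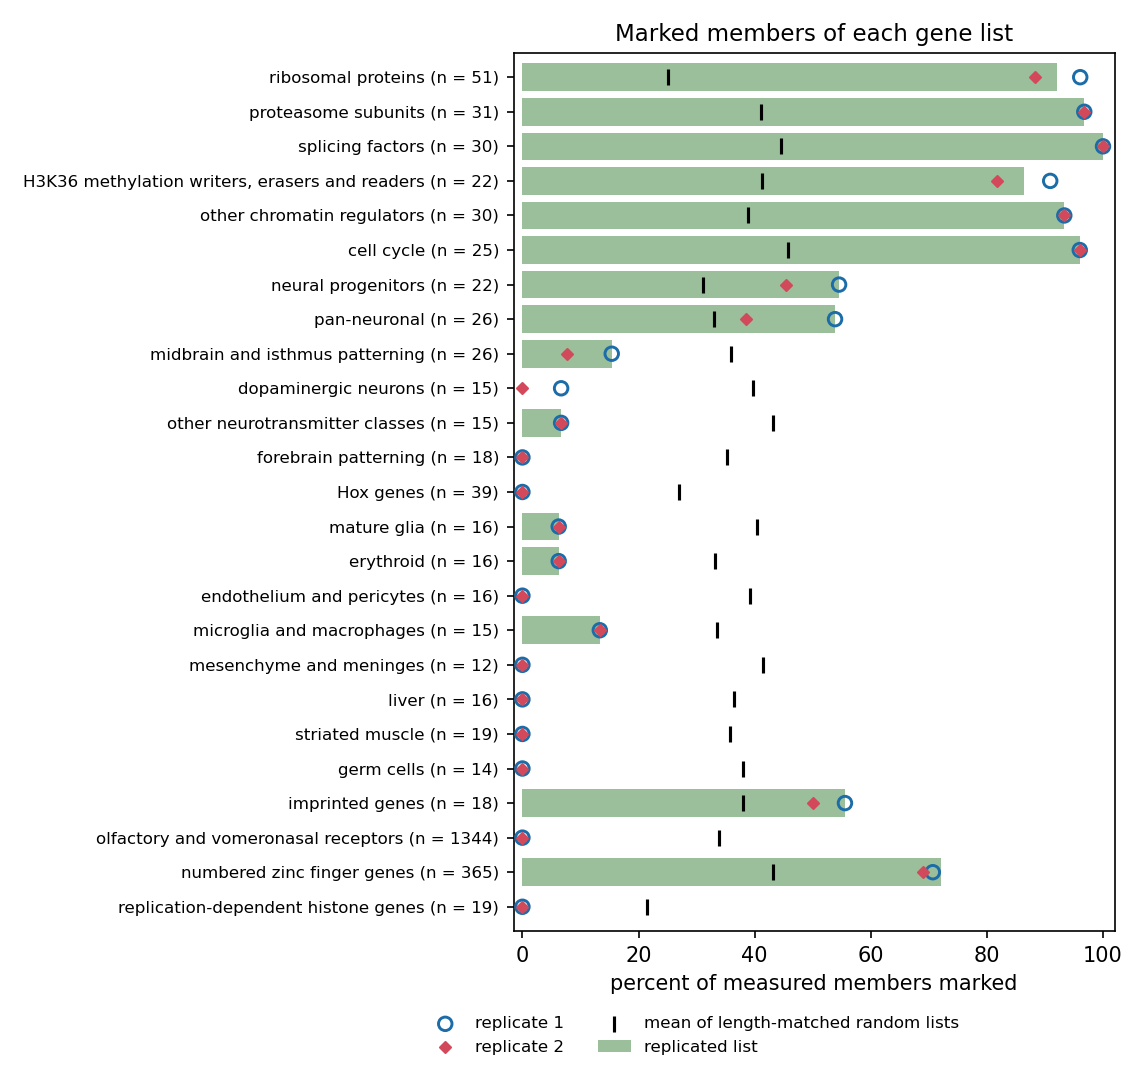
Percent of measured members that were marked (x axis) in each of 25 gene lists (y axis; n is the number of measured members): bars give the replicated list, open circles replicate 1, diamonds replicate 2, and black ticks the mean of random lists matched on gene length. Housekeeping, chromatin and cell cycle lists reach 86.4% to 100%, and the lists of other cell types and tissues lie between 0% and 13.3%.

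The X chromosome carried far less of the mark than any autosome. Of 877 X-linked genes 107 were marked (12.2%; 11.6% ± 3.63 in the replicates), against 39.3% of autosomal genes (37.5% ± 2.59). Autosomes ranged from 30.3% on chromosome 14 to 49.95% on chromosome 8. The X was 0.557% covered (0.665% in replicate 1 and 0.340% in replicate 2), while the least covered autosome, chromosome 3, was 2.98% covered (2.83% and 2.12%). None of the 163 genes on the Y chromosome was marked. The pools also held female embryos, so a missing peak there need not mean that the mark was absent. In proportion to its peaks the X also differed most between replicates, with 2755 peaks in replicate 1 and 1633 in replicate 2.

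**Figure D4:**
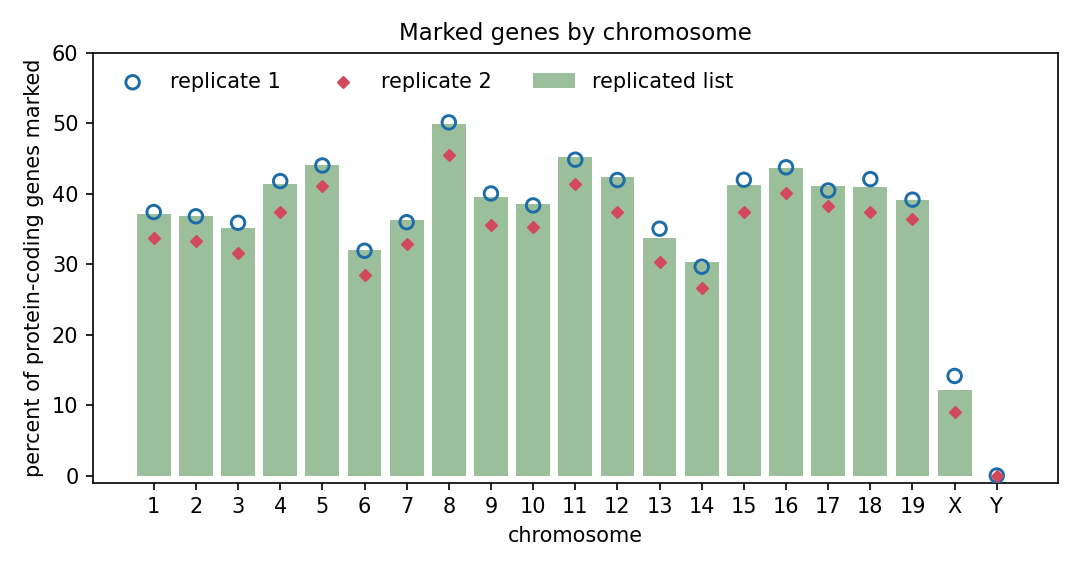
Percent of protein-coding genes marked (y axis) on each chromosome (x axis); bars give the replicated list, open circles replicate 1 and diamonds replicate 2. Autosomes lie between 30.3% and 49.95%, the X at 12.2% and the Y at 0%.

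The 10 genes that differed most between replicates were all covered more in replicate 1. Among 5823 genes of at least 10 kb and 10% mean coverage, replicate 1 exceeded replicate 2 by a median of 7.79 points (SD 4.93 across genes). The largest gaps were in Becn1, an autophagy regulator (53.7% ± 24.6), the thymidine kinase Tk1 (38.7% ± 23.9) and Med12 of the Mediator complex (46.3% ± 23.2). Zscan22, Ilvbl, Hdac6, Ehbp1l1, Rpp30, Txndc15 and Gm49027 followed, with SDs of 19.2 to 20.95 points. Med12 and Hdac6 are X-linked, and Becn1, Tk1 and Gm49027 overlap another coding gene.

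Outside annotated genes the mark was scarce. Replicated peaks more than 5 kb from any gene formed 197 clusters over 0.211 Mb, 0.184% of all covered bases, and 56 of them overlapped a gene or pseudogene in the RefSeq annotation of the same build. The 5 largest were on chromosome 4 (91210983 to 91231084, 11.2 kb covered; 7.44 ± 3.15 kb in the replicates), chromosome 9 (56067209 to 56082817, 7.82 kb; 6.14 ± 1.31), chromosome 10 (79051042 to 79059089, 5.46 kb; 3.58 ± 0.969), chromosome 5 (104582124 to 104588294, 4.85 kb; 3.88 ± 0.301) and the Y chromosome (90738646 to 90745838, 4.50 kb; 3.38 ± 1.31). In RefSeq, the first lies in the neuronal RNA-binding gene Elavl2, the next in Pstpip1, the fourth in Zfp33b and the last in Gm52481, while the cluster on chromosome 10 lies in no gene. The number of clusters depended on the peak list and the distance: replicate 1 alone gave 826 and replicate 2 alone 609, and 29 clusters lay more than 20 kb from a gene.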

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

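Of the replicated peaks, 15 lay on unplaced or unlocalised scaffolds, outside the chromosomes used in all comparisons. They are named because no comparison used them, and no test was made. They fell on 8 scaffolds, and the strongest had a signal value of 10.2. The replicates' own lists had 42 and 29 such peaks. No list had a peak on the mitochondrial genome.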

How the results depend on the processing

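No result changed direction under the alternatives run. The comparison of low gene lists by marked members and the removal of overlapping genes from the lists were chosen after seeing the data. Of 61 alternatives to the main results, 36 stayed within the replicate SD, within 1.5 times for counts, or within the Wilson interval for shares. Some of the 36 could hardly move. Of replicated peaks, 99.5% already had a q-value of 0.01 or less. For measures judged by an SD, each single-replicate value was set against an SD made from the same 2 values. The other 25 alternatives are given here, and where no reason is stated the cause was not tested. With any overlap of 1 base, 62.4% of replicate 1 peaks and 80.7% of replicate 2 peaks were shared. With 90% of the peak, 15.9% and 44.4% were, and the looser or stricter rule moves these by construction. With q-values of 0.01 or less the shares were 45.5% and 73.2%, and with the same number of peaks 50.01% and 68.9%. The replicated list held 74.1% and 86.4% of the 2 replicates' peaks at 1 base and 67.7% and 83.1% at 90%. The genic share was 95.4% in the pooled list and 94.7% with coding genes only. Of genes that overlap no other gene, 3453 were marked, in a smaller set. The share marked can fall as well: it was 33.7% in coding genes outside other coding genes, against 37.9% of all coding genes. The 3' to 5' ratio was 2.02 in genes of at least 50 kb, and 1.88 to 1.98 with 1 replicate left out. The exon to intron ratio was 1.64 without last exons, 1.60 with exons of at most 300 bases, and 1.49 to 1.60 with 1 replicate left out. Autosomal genes were marked in 35.7% to 39.4% of cases with 1 replicate left out. Intergenic clusters numbered 1184 at 1 kb and 29 at 20 kb, by construction, and 609 to 826 in single replicates. Marked genes numbered 6725 to 10351 over the other thresholds and lists. The number of gene lists above random ones was 7 to 10, against 9, and of those below 13 or 14, against 14. The median of a list moved past its replicate SD in 12 of 100 cases. Lists with a median of 0 stayed at 0 throughout, so they could not show a move. With replicate 1 left out, the median of every other list fell past its SD, as in neural progenitors, from 15.3% to 6.99%. No paired analysis was possible because there is 1 group. Depth is unknown, and replicate 2, with fewer covered bases, lost 863 genes that replicate 1 marked.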

Other observations

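The tests of weak peaks as the whole cause of the X difference and of gene content as part of it, and the gene families and non-coding genes described first, were chosen after the gene results were seen. Members of 8 families were also revised after a first count, by what the genes encode. Among gene families picked by symbol, those of basic cell machinery were mostly marked. Of 75 mitochondrial ribosomal protein genes 66 were marked, against a mean of 26.3 in 1000 random lists matched on length, as were 33 of 37 aminoacyl-tRNA synthetases (random mean 16.45), 45 of 53 DEAD and DEAH box helicases (24.4), 40 of 46 translation initiation factor genes (18.96), 31 of 35 NADH dehydrogenase subunits (12.8), 24 of 28 RNA polymerase subunits (11.02), 23 of 25 exosome and Integrator subunits (10.7), 51 of 65 sorting nexin and VPS genes (25.998) and 41 of 55 ubiquitin-specific proteases (22.1). Families of excitability and of other tissues were mostly bare: 7 of 89 potassium channel genes were marked (31.96), 3 of 47 glutamate and GABA receptor genes (14.9), 2 of 44 collagens (14.3), 1 of 80 cytochrome P450 genes of families 1 to 4 (36.5), 1 of 66 chemokine and interleukin genes (19.8), and none of 70 genes of keratins and keratin-associated proteins (21.06) and 39 beta-defensin genes (9.71). The 3 receptor genes were Grik5 (77.9%), Gabbr1 (72.5%) and Grin3b (45.9%), and the 2 collagens Col2a1 (65.3%; 57.3% ± 5.52 in the replicates) and Col11a2 (11.5%). Of 43 forkhead genes 6 were marked, against a random mean of 13.4 (range 4 to 25), led by the proliferation factor Foxm1 (68.1%). Of 19 Sox genes 6 were, near the random mean of 5.33 (range 0 to 13), led by Sox15 (67.5%), and 5 and 4 were in the replicates. Grin3b, Foxm1 and Sox15 overlap another coding gene. Of 68 protocadherin genes 23 were marked, against 19.2. Of these, 21 belong to the gamma cluster, whose annotated genes overlap and share 3' exons, from Pcdhgc3 (21.2%) to Pcdhga3 (44.5%), and the others were Pcdh18 (69.5%) and Pcdh8 (22.5%).

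Of the 112 marked long non-coding RNA genes outside coding genes, the examples here were picked by name. Some of the 112 carry symbols of coding genes although the annotation gives them a non-coding class, among them Trerf1, Zswim6 and Tctn2. Rmst, expressed in the midbrain, had 16.1 kb covered (17.1% of its body; 14.3% ± 6.58), Crnde 48.8% (34.9% ± 4.91), Pantr1 15.3% (11.9% ± 3.31), Mir9-3hg 22.2% (18.0% ± 6.59) and the abundant nuclear RNA Malat1 50.5% (47.0% ± 7.17). At the imprinted Dlk1 locus on chromosome 12, the maternally expressed RNAs Meg3, Rian and Mirg had 37.1% (24.2% ± 12.3), 14.8% (14.5% ± 4.54) and 50.4% (35.8% ± 3.63). Rtl1, which lies between Meg3 and Rian, had 42.7%, and Dlk1 itself 0%. Outside these 112, the imprinted RNA H19 had 0%. The antisense RNAs Airn (3.63%) and Kcnq1ot1 (7.55%) overlap the coding genes Igf2r (55.5%) and Kcnq1 (2.19%), and as coverage ignores strand it cannot be assigned to either gene of a pair.

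Of the 100 replicated peaks with the highest signal value, 42 overlapped a numbered zinc finger gene, against 2.05 expected from their share of all peaks, and 39 and 41 of the top 100 did in the 2 replicates. The first was at Zfp146 (chromosome 7, 30160611 to 30164394, signal value 16.53), and 37 of the 42 overlapped the last exon of a coding gene. Numbered zinc finger genes encode their finger arrays in the last exon, but the exon overlapped was not required to be their own. Reads shared between identical stretches of sequence did not account for the number of zinc finger peaks. A median of 96.6% of the 32-base words in these 42 peaks, and at least 82.8% in each, occur once in the genome. In 30 of the 42 at least 95% of words did. Near-identical words count as different here and the aligner is unknown, so reads shared between near-identical copies cannot be ruled out. Width and GC content of the strongest peaks, as matched here, did not account for the number. In 1000 draws of other peaks matched on both, at most 12 were zinc finger peaks. The matched sets drawn from left out the 100 strongest peaks, and the smallest held 9 peaks. Last-exon peaks of all these genes had a median signal at only the 66.0 percentile of other last-exon peaks of the same GC content and width. That value lay between the ranges set for and against. No biological explanation was tested, since the design holds no second group. A candidate explanation is the H3K36me3 domain known at the 3' exons of such genes. On it these data add only the overlap with last exons of coding genes.

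The X chromosome had fewer marked genes than any autosome. Gene content may account for part, since at the autosomal rate of each promoter class 30.3% of X-linked genes would be marked, against 39.3% on autosomes and 12.2% seen. Promoter class did not account for all of it. Of 253 X-linked genes with a CpG-rich promoter 27.3% were marked (Wilson 95% interval 22.2% to 33.1%), below the lowest autosome at 54.4%. With any pooled peak counted the gap in that class was 67.2% against 83.7%. X-linked and autosomal genes were not matched on length or function, so gene content as the whole cause cannot be excluded. Weak peaks may account for part. With any pooled peak counted, the ratio of X to autosome rose by 1.96 times, from 0.310 to 0.610, and the gap shrank from 27.1 to 21.6 points. This changed both list and threshold (0.389 for the pooled list at 10%). Weak peaks that were called did not account for all of it. Of X-linked genes 33.8% had any pooled peak (30.7% to 36.9%), against at least 44.3% on every autosome. The pooled list has its own threshold, and its X peaks were weaker (median −log10 p-value 5.69 against 6.80 on autosomes). Uncalled X-linked peaks as the whole cause therefore cannot be excluded. What stays open is gene content beyond promoter class and X-linked peaks too weak to be called. The single active X in each cell, a control with another share of X reads, and gene activity itself also stay open. None of these was tested.

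Replicate 2 listed fewer X-linked peaks, 1.00% of its peaks against 1.53% in replicate 1. A general loss of weak peaks in replicate 2 did not account for it. Of pooled X peaks, 30.6% were found in replicate 2 and 66.8% in replicate 1, a difference of −36.2 points. Of autosomal peaks at the same pooled p-values, 34.51% were found in replicate 2 and 56.97% in replicate 1. Single autosomes lay between −23.9 and −20.8 points. The wider gap on the X thus came more from a higher share in replicate 1 than from a lower share in replicate 2. Whether enrichment on the X over control differed cannot be told apart from no difference. At the 491 X peaks found in both replicates, 18.5% of the pooled X peaks, the median log2 signal ratio relative to autosomes was 0.0. Its bootstrap 95% interval (−0.036 to 0.035) was wider than the autosomal range of −0.022 to 0.0094, and peaks found in only 1 replicate do not enter it. A different mix of male and female embryos in the 2 pools, or in their controls, stays open and was not tested.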
